A study of Mus musculus with 12 samples.

How the data were processed

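RNA was measured in thymocytes sorted from mice in which both copies of the zinc finger genes Zfp148 and Zfp281 carry loxP sites. In the double knockout (dKO) libraries Cre recombinase driven by the Cd4 promoter removes the floxed parts of both genes in developing T cells, and the controls carry the floxed genes without Cre. 2 populations were sorted, an immature CD4 single-positive gate (ImCD4: CD44 low, CD4 positive, CD8 negative, H2-Kb negative, CD69 positive) and an immature CD8 single-positive gate (ImCD8: CD44 low, CD8 positive, CD4 negative, TCR beta positive, CD69 positive). There were 12 libraries in 4 groups of 3. Per the labels' protocols, RNA came from a column kit for small samples and libraries from a SMARTer low-input kit.

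Per the submitters' processing notes, the authors used cutadapt 1.18, STAR 2.6.1 and HTSeq with the mm10 genome. The gene annotation and the strand setting are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. The deposited values are raw whole-number counts per gene symbol, with no normalization. Each library's table holds 53656 gene rows and 5 summary rows. The summary rows stayed out of library sizes and tests: reads outside any gene made up 10.5% to 16.4% of the tallied reads, ambiguous reads 5.37% to 5.82% and reads with more than 1 alignment 3.87% to 5.39%.

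Groups follow the sample titles. For the 6 ImCD8 libraries the title and the genotype label are opposite: the libraries titled control are marked as carrying Cre and those titled dKO as lacking it. The levels of Zfp148 and Zfp281 go with the titles in all 12 libraries and against the genotype label of the 6 ImCD8 libraries, and every direction given for ImCD8 rests on the titles. Because controls lack Cre, an effect of Cre itself is not separated from the loss of the 2 genes. Nothing in the labels says that libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be partly technical. Replicate numbers only name libraries in the order of their records. Within-group pairs of libraries differed by more than counting noise, with a chi-square per degree of freedom of at least 3.73, so none was counted as a repeat.

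Gene counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its minimum count of 10 and minimum total of 15, which left 13383 genes, and libraries were scaled by trimmed means (TMM factors 0.946 to 1.04). All 12 libraries entered 1 quasi-likelihood model with 4 group means and 8 residual degrees of freedom, fitted with robust settings. Contrasts were dKO against control in ImCD4, the same in ImCD8, the difference of these 2 effects, and ImCD8 against ImCD4 in controls and in dKO. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes, and 0.05 was the threshold. Adjusted p-values without another name come from this test. Levels are counts divided by the TMM-scaled library size on the usual CPM scale, as mean ± SD with n = 3, and log2 fold changes carry a standard error (SE). A comparison of 3 against 3 by exact permutation cannot go below p = 0.1.

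Before the data were examined, 27 gene lists were fixed and 23 had at least 5 tested members. They were tested with camera in limma 3.58.1 on log2 CPM with a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were alternatives. The lists of germline genes (0 tested members), B cell markers (3), myeloid and dendritic markers (4) and erythroid and platelet markers (4) were not tested as lists.

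Genes named in the text were chosen by a rule fixed before the data were examined. It takes the targeted genes, the 10 largest rises and 10 largest falls in each dKO contrast and 6 of each in the control lineage contrast. These had to pass the threshold, reach 5 CPM in the higher group and show no overlap between the libraries of the 2 groups. Predicted and clone names, pseudogenes, receptor segments and sex-linked markers were left out. The rule adds the 5 smallest p-values in each direction for the difference, up to 4 members of each list per dKO contrast, every called member of the CD4-lineage and CD8-lineage lists and the 2 most abundant members of each contaminant list. Nkg7 is named outside this rule, and some genes that the rule takes are not reported here.

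Alternatives were RLE size factors, library size alone, DESeq2 1.42.0, limma-voom with quality weights, no filter, a filter of over 5 CPM in 3 libraries, a 2-fold minimum, only the 6 libraries compared and each library left out in turn. A sex term was not run because all 12 libraries expressed Y-linked genes. 2 alternatives were added after the data were seen, both for 4 libraries, 1 in each group, that stood apart on the third principal component: leaving them out, and a model term for them. That term was itself taken from these counts. The other 8 libraries were lower on that component.

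The scripts were tested on simulated counts with the control means of each population and the real dispersions and library sizes. Genes were drawn independently, with no variation shared between libraries, and far fewer were changed than were called in ImCD4. Recovery and false calls in the real data may therefore differ. For ImCD4, 86.6% of 67 genes changed by 1 on the log2 scale were recovered and 41.8% of 67 changed by 0.5, with 9 of 13008 unchanged genes called. For the difference between lineages 66.7% of 66 genes changed by 1 and 20.9% of 67 changed by 0.5 were recovered. Coordinates are from GENCODE M21 on GRCm38, the assembly that mm10 names. Of the tested symbols 80.8% were found in that annotation, which was not necessarily the one the authors used. Floors for genes with 0 counts are 3 counts over the 3 libraries of a group and cover counting error only, since PCR reads without molecular identifiers are not independent molecules.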

Results

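Messenger RNA was counted in 12 libraries of immature thymocytes, 3 each of control ImCD4, dKO ImCD4, control ImCD8 and dKO ImCD8. Gene counts per library ran from 7315833 to 10943143, and 18504 to 20305 genes had at least 1 count. Libraries of a group correlated at 0.983 to 0.992 in log2 CPM. The first principal component carried 66.1% of the variance and separated the ImCD4 from the ImCD8 libraries. The second carried 11.9% and separated dKO from control. The third carried 5.31% and set apart 1 library of each group, 4 in all, in each case the last listed of its group (replicate 3).

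The targeted genes were lower in every dKO library than in any control library of the same population. Zfp148 (ENSMUSG00000022811.17, chromosome 16, 33380836 to 33504363, plus strand) fell from 180.2 ± 3.01 to 66.5 ± 3.13 CPM in ImCD4 (SD, n = 3) and from 165 ± 4.84 to 54.9 ± 8.70 CPM in ImCD8. Its log2 fold changes were -1.44 ± 0.09 and -1.59 ± 0.09 (SE), with edgeR adjusted p = 4.43e-08 and 2.63e-08. Zfp281 (ENSMUSG00000041483.14, chromosome 1, 136624901 to 136630053, plus strand) fell from 486 ± 65.6 to 18.6 ± 2.62 CPM in ImCD4 and from 119 ± 7.93 to 12.8 ± 2.36 CPM in ImCD8. Its log2 fold changes were -4.71 ± 0.13 and -3.22 ± 0.14, with edgeR adjusted p = 5.47e-12 and 2.97e-09. In each population the exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 allows. Which exons are floxed is not given in the sources used here, so the counts that remain do not measure intact transcript. The levels go with the titles of all 12 libraries and against the genotype label of the 6 ImCD8 libraries.

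**Figure D1:**
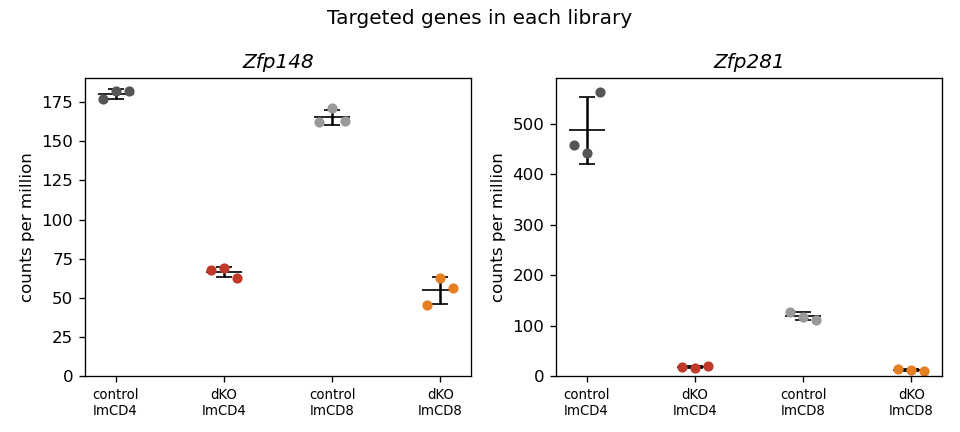
Zfp148 and Zfp281 in each library in CPM, with points for libraries and bars for mean ± SD (n = 3). Zfp281 lies between 16.2 and 21.4 CPM in the ImCD4 dKO libraries and between 441 and 562 CPM in their controls.

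The first comparison asks what losing both factors changes in immature CD4 thymocytes. Slc12a8, a solute carrier gene (ENSMUSG00000035506.16, chromosome 16, 33517328 to 33664135, plus strand), rose from 0.340 ± 0.203 to 49.3 ± 2.12 CPM. Sox13, a transcription factor gene of gamma-delta T cells, rose from 20.3 ± 1.39 to 218 ± 58.7 CPM, and the myosin gene Myo6 from 63.7 ± 14.5 to 636 ± 205 CPM. Chd3, which encodes a chromatin remodeller (ENSMUSG00000018474.17, chromosome 11, 69343273 to 69369406, minus strand), fell from 309 ± 53.5 to 22.8 ± 5.50 CPM, and the creatine kinase gene Ckb from 477 ± 50.8 to 40.6 ± 12.7 CPM. In all, 1797 of 13383 genes passed the threshold, 972 higher and 825 lower in dKO, and 388 of them changed at least 2-fold, 130 higher and 258 lower. Which direction had more genes depended on the setting: with library size only 757 were higher and 853 lower. The ImCD4 groups also differed without overlap in gene counts, 8276742 to 9173424 in control and 9319732 to 10943143 in dKO. The same held for reads outside any gene, 13.6% to 16.4% in control and 10.49% to 12.9% in dKO. It also held for ambiguous reads, 5.37% to 5.46% and 5.55% to 5.67%, and for the mitochondrial share of counts, 1.07% to 1.31% and 0.633% to 0.961%. TMM factors were 1.028 to 1.036 and 1.005 to 1.026. Chance gives such a separation for 10% of measures. Depth and these library measures thus go with genotype in ImCD4 and are not separated from it.

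Ntn4, Usp44, Pdgfb, Lgals3, Myo1e and Aqp9 were also among the largest rises. Ntn4, a netrin gene, had 1 count over the 3 control libraries and 365 over the 3 dKO libraries, a ratio of 318 with a 95% counting interval of 56.6 to 12576. The water channel gene Aqp9 rose by 1.95 ± 0.11 on the log2 scale, from 22.1 ± 1.87 to 85.5 ± 1.52 CPM. Among the largest falls, the matrix metalloproteinase gene Mmp9 went from 25.1 ± 5.82 to 0.596 ± 0.250 CPM and the zinc finger gene Zfp467 from 63.1 ± 11.4 to 3.34 ± 0.438 CPM. Pde4c, Serpinb9, Cacnb3, Ptprn and Rundc3a also fell.

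**Figure D2:**
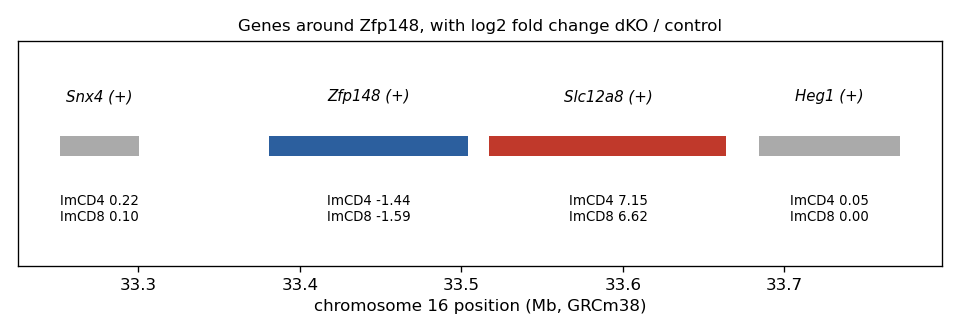
Zfp148 and the nearest named tested genes on chromosome 16 of GRCm38, drawn to scale in Mb, with the log2 fold change of dKO over control in each population under each gene. Slc12a8 starts 12965 bp after the end of Zfp148 on the same strand and changed by 7.15 and 6.62, while Snx4 and Heg1 did not pass.

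Of the 10 CD4-lineage genes, 1 rose, 1 fell and 8 did not pass. The costimulatory receptor gene Icos fell by 0.55 ± 0.08 on the log2 scale (adjusted p = 0.000192) and Ctla4 rose by 1.16 ± 0.21 (adjusted p = 0.00178). Zbtb7b, which encodes the CD4-lineage factor ThPOK (chromosome 3, 89377644 to 89394776, minus strand), measured 291 ± 84.5 CPM in control and 165 ± 61.8 CPM in dKO. Its log2 fold change of -0.82 ± 0.25 did not pass (adjusted p = 0.0607). Its levels were 247, 236 and 388 CPM in the control and 138, 122 and 236 CPM in the dKO libraries, so that much of the spread within each group lay in replicate 3, which stood apart on the third component. It passed in 5 of 11 alternatives, among them DESeq2 (adjusted p = 0.00620) and limma-voom (0.00215), and the adjusted p ran from 2.32e-08, with a term for the 4 libraries chosen after the data were seen, to 0.177. Of the 18 CD8-lineage and cytotoxic genes, Cst7 and Runx3 rose and 16 did not pass. Runx3, a factor of the CD8 lineage, rose by 0.36 ± 0.11 (adjusted p = 0.0360). Both calls were lost when single libraries were left out, with an adjusted p of up to 0.149 for Runx3 and 0.0605 for Cst7. Adjusted over the list alone, 2 CD4-lineage genes rose and 2 fell, and 2 CD8-lineage genes rose and 1 fell.

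Cytokine receptor genes moved in both directions, 5 higher and 3 lower of 20, and 6 and 3 adjusted over the list alone. Il4ra rose from 228 ± 5.39 to 481 ± 31.4 CPM and Il2rb from 35.8 ± 2.99 to 69.4 ± 3.09 CPM, while the common gamma chain gene Il2rg fell by 0.55 ± 0.07 on the log2 scale. Of 19 mature single-positive genes 5 rose and 3 fell, and 8 and 3 adjusted over the list alone. The transcription factor gene Klf2 rose by 0.92 ± 0.14 and Slfn1 by 0.87 ± 0.11, whereas the chemokine receptor gene Ccr7 fell by 1.08 ± 0.11, from 608 ± 107 to 288 ± 25.3 CPM. Among 23 genes induced by T cell receptor signals 2 rose and 2 fell, as when adjusted over the list alone: Dusp2 and Myc were higher, and Cd5 and Cd6 lower, Cd5 by -0.73 ± 0.14. Of 21 receptor-complex genes 2 rose and 4 fell, as when adjusted over the list alone, with Cd247 and Grap2 among those lower and Ptpn22 among those higher. Of 16 glycolysis genes 6 rose and 2 fell, and 9 and 3 adjusted over the list alone. The glucose transporter gene Slc2a3 fell by 0.78 ± 0.08 and Pkm by 0.77 ± 0.09, and Aldoa rose by 0.70 ± 0.07. Of 26 cell cycle genes 5 rose and none fell, as when adjusted over the list alone, among them the replication genes Mcm2, Mcm5 and Mcm7. The calls of Myc, Ptpn22 and Mcm5 were lost without single libraries, with an adjusted p of up to 0.0581, 0.0751 and 0.122.

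2 lists passed the camera test, both higher in dKO. The same genes passed when adjusted over the list alone. Of 8 innate-like T cell genes Il2rb and Cd44, whose protein was gated low in the sort, rose (camera adjusted p = 0.0236, and 0.230 with an estimated correlation). Of 7 gamma-delta T cell genes Sox13 and Tcrg-C1 rose (adjusted p = 0.0413, and 0.241 with an estimated correlation). Other splits of the same 6 libraries gave up to 8 such lists. Each of those splits mixes control and dKO libraries in unequal numbers, keeps part of the dKO effect and is no reference without change. A count of lists also does not speak to particular ones, so chance stays open for these 2 calls. Both were lost without control replicate 3 or dKO replicate 1, with an adjusted p of up to 0.0739 for the innate-like and 0.108 for the gamma-delta list, and the gamma-delta call also without the 4 libraries apart on the third component (0.0506). Among genes of other cell types, Ighm, Cst3, Ly75 and Ctsl did not pass, and the erythroid-list gene Car2 rose from 4.93 ± 0.827 to 10.7 ± 2.51 CPM. Of the 5 tested thymic epithelial markers 1 rose, and adjusted over the list alone 2 rose and 2 fell. The count of changed genes was 1086 without control replicate 1 and 1055 without dKO replicate 2.

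The same question was asked of immature CD8 thymocytes, with directions that rest on the titles of the libraries. Slc12a8 rose from 0.322 ± 0.0993 to 32.3 ± 2.02 CPM, and the chemokine receptor gene Ccr8 from 20.9 ± 8.58 to 86.9 ± 22.2 CPM. Chd3 fell from 176 ± 16.2 to 7.01 ± 2.57 CPM, and Ddc, a decarboxylase gene, from 25.5 ± 1.54 to 2.22 ± 0.740 CPM. In all 822 of 13383 genes passed, 350 higher and 472 lower, and 231 changed at least 2-fold. Without the filter 667 were higher and 613 lower.

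Ntn4, Cd163l1, Aqp9, Il17rb, Pcsk1, Chdh and Cyp2s1 were also among the largest rises. Aqp9 rose by 3.17 ± 0.16 on the log2 scale and the cytokine receptor gene Il17rb by 2.69 ± 0.26. Serpinb9, Zfp467, Rundc3a, Ptprn, Zp3r, Ccl5 and Ckb were among the largest falls. The chemokine gene Ccl5 measured 44.2 ± 31.2 CPM in control and 4.49 ± 2.20 CPM in dKO, and the control libraries differed widely. Ccr8 lost its call without the 4 libraries apart on the third component (adjusted p = 0.0588).

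Of the 18 CD8-lineage and cytotoxic genes none rose, 5 fell and 13 did not pass. Besides Ccl5, the granzyme gene Gzmb fell by 2.56 ± 0.50, the perforin gene Prf1 by 1.41 ± 0.27, Ctsw by 0.44 ± 0.08 and the integrin gene Itgae by 0.34 ± 0.08 on the log2 scale. Control replicates 1, 2 and 3 had 7.51, 3.38 and 16.8 CPM of Gzmb and 37.0, 37.9 and 61.0 CPM of Prf1. Ccl5 was also highest in control replicate 3, so the falls of these genes may not be independent. Adjusted over the list alone 8 fell and 1 rose. Of the 10 CD4-lineage genes Cd40lg rose by 1.01 ± 0.19 and Gata3, a factor of CD4 and Th2 cells, by 0.48 ± 0.10, and Icos fell by 0.53 ± 0.08. Adjusted over the list alone 5 rose and 2 fell. Cd40lg had 3.14 to 5.07 CPM in control and 6.03 to 8.51 CPM in dKO, against 244 to 296 CPM in control ImCD4. Gata3 had 46.2 to 57.0 CPM in control and 62.4 to 77.7 CPM in dKO, against 362 to 389 CPM in control ImCD4. Zbtb7b had 2 counts over the control and 3 over the dKO libraries, at the floor. Among transcription regulators Id2 fell from 195 ± 39.8 to 77.6 ± 10.6 CPM and Id3 rose from 257 ± 18.7 to 358 ± 42.2 CPM. Il4ra rose by 0.84 ± 0.07 and Il6ra by 1.21 ± 0.28, and Slc2a3 fell by 1.73 ± 0.09. Without single libraries the calls of Itgae and Il6ra were lost, with an adjusted p of up to 0.0782 and 0.103.

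3 lists passed the camera test. The list of CD8-lineage and cytotoxic genes was lower (adjusted p = 0.00956, and 0.483 with an estimated correlation), and its call was lost with the stricter filter (0.0557). The cell cycle list was lower, with Mcm3 the only called member of 26, over all genes and adjusted over the list alone (adjusted p = 0.0220, and 0.525 with an estimated correlation). Without single libraries the call of Mcm3 was lost, with an adjusted p of up to 0.138. The call of the cell cycle list was lost without control replicate 1 or 2 or dKO replicate 3, with an adjusted p of up to 0.173. This list also loads on the third component, and without the 4 libraries apart on it the list was lower (adjusted p = 8.10e-08). The list of T helper cytokine and Th2 genes was higher, with Il4ra, Ccr8 and Gata3 called among 6 either way (adjusted p = 0.0345, and 0.476 with an estimated correlation). Its call was lost without control replicate 1 or 3 or dKO replicate 2, with an adjusted p of up to 0.0666, and without the 4 libraries apart on the third component (0.0979). Other splits of the same 6 libraries gave up to 9 such lists. They too mix control and dKO libraries in unequal numbers and are no reference without change, so chance stays open for these 3 calls. The B cell gene Cd79b rose from 10.1 ± 1.79 to 25.3 ± 7.59 CPM, while Ighm, at 335 ± 46.6 and 387 ± 63.4 CPM, did not pass. Of the 5 tested thymic epithelial markers 1 rose, and 2 rose adjusted over the list alone. The count of changed genes was 473 without control replicate 1.

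**Figure D3:**
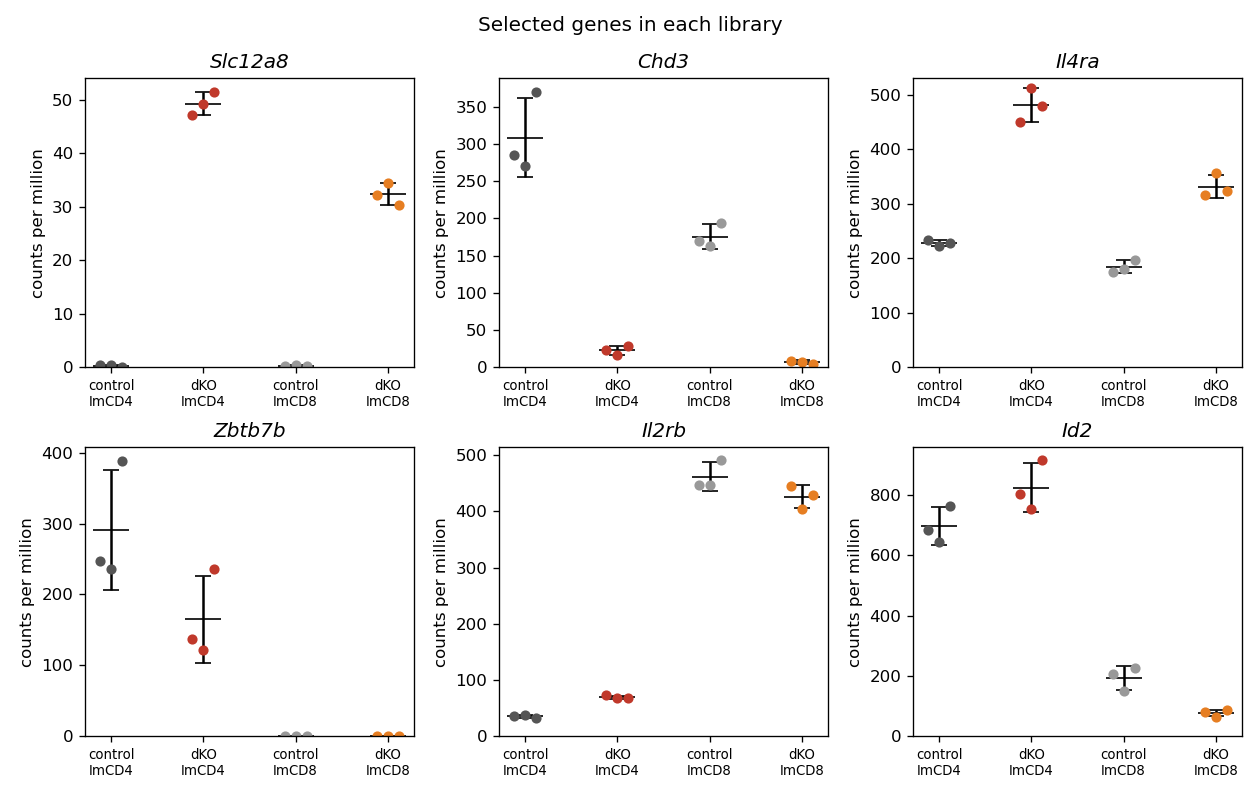
6 genes in each library in CPM, with points for libraries and bars for mean ± SD (n = 3). Slc12a8 and Il4ra are higher and Chd3 lower in both dKO groups, Il2rb is higher in ImCD4 dKO and Id2 lower in ImCD8 dKO; Zbtb7b in ImCD4 did not pass the test.

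The effects were then compared between the populations, which share no library, with ImCD8 directions taken from the titles. 490 genes were called in both in the same direction and 7 in opposite directions. Of these 190 were higher in both, against 25.4 for independent lists, and 300 lower in both, against 29.1. That reference takes each gene as equally likely to be called, whatever its expression level, and may be too low. Chd3, Serpinb9, Zfp467, Rundc3a, Ptprn and Ckb fell in both, and Slc12a8, Ntn4, Aqp9, Il4ra, Cd44, Dntt and Bbc3 rose in both. Across the 13383 genes the log2 fold changes correlated at 0.512 (Pearson) and 0.434 (Spearman); genes are not independent replicates. Genes lower in ImCD4 dKO had a median of -0.36 in ImCD8 (camera p = 1.61e-54, and 1.05e-06 with an estimated correlation). The number called in both was 312 without control ImCD8 replicate 1.

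**Figure D4:**
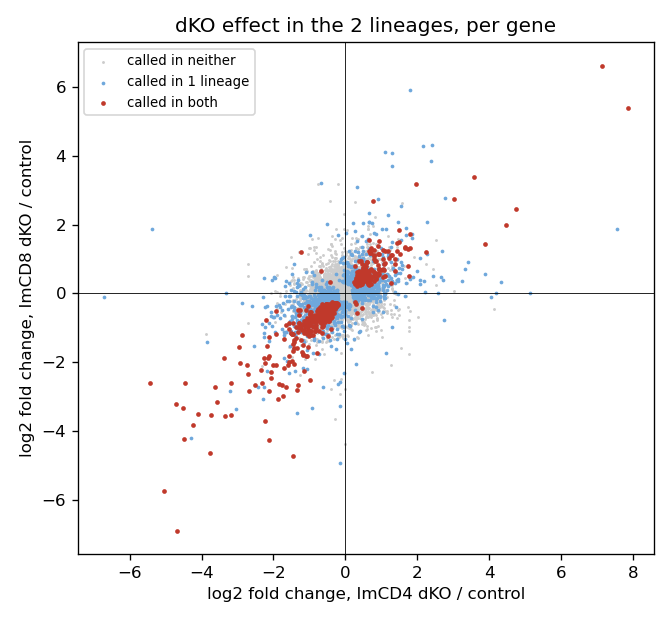
Log2 fold change of dKO over control for each of 13383 genes, ImCD4 on the x axis and ImCD8 on the y axis, coloured by whether a gene was called in neither, 1 or both. The 490 genes called in both with the same sign lie in the upper right and lower left corners.

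The size of the effect differed between the populations for 58 genes, 34 with a more positive change in ImCD4 and 24 with a more positive change in ImCD8. Il2rb rose in ImCD4 and changed by -0.12 ± 0.07 in ImCD8, a difference of 1.07 ± 0.11 (adjusted p = 0.000159). Cd160 and Uhrf1, a gene of DNA methylation upkeep, showed differences of 1.39 ± 0.16 and 1.09 ± 0.13. Slc2a3 fell more in ImCD8, and Zdhhc15 fell more in ImCD4 with a difference of -1.45 ± 0.13. Mn1 and the phosphatase gene Dusp10 fell in ImCD4 and rose in ImCD8, Mn1 with changes of -1.23 ± 0.22 and 1.20 ± 0.25. Zfp281 itself fell more in ImCD4, where its control level was higher. The count depended on the setting: DESeq2 called 140 genes, 233 were called without the filter, 106 without the 4 libraries apart on the third component and 200 with a term for them.

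Control ImCD8 and control ImCD4 cells differed in 6058 genes, 3097 higher and 2961 lower in ImCD8, and 2675 higher and 3546 lower with library size only. Itgae rose from 1.15 ± 0.141 CPM in ImCD4 to 816 ± 4.67 CPM in ImCD8, and H2-Q6 and Gzmb were also among the largest rises. Fam46a, Golm1 and Gzmk had no count in control ImCD4 and were at least 100-fold, 66.1-fold and 59.8-fold higher in ImCD8. Control ImCD8 replicate 3 carried much of this for Golm1 and Gzmk, whose bounds without it were 36.5-fold and 34.2-fold. Zbtb7b had 7899 counts over the 3 control ImCD4 libraries and 2 over the 3 control ImCD8 libraries. Mmp9, Akr1c18, Hap1, Prlr and Cdh3 had no count in control ImCD8, and Mmp9 was at least 212-fold lower there. All 18 CD8-lineage genes were higher in ImCD8 (camera adjusted p = 1.30e-14, and 0.0693 with an estimated correlation), 9 of 10 CD4-lineage genes were lower (1.62e-07, and 0.106) and all 26 cell cycle genes were higher (2.40e-13, and 0.119), with the same counts adjusted over the list alone. The ImCD4 gate is negative for H2-Kb and the ImCD8 gate names no such marker, so the 2 gates differ in more than lineage.

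Between dKO ImCD8 and dKO ImCD4 5853 genes differed, 2960 higher and 2893 lower in ImCD8, and 2548 higher and 3435 lower with library size only. There 17 of 18 CD8-lineage genes were higher and 9 of 10 CD4-lineage genes lower in ImCD8, and all 20 interferon genes were higher, against 18 of 20 in control. None of these lists held in camera with an estimated correlation, the adjusted p being 0.0901, 0.0903 and 0.107. That setting called no list in any contrast, not even the CD8-lineage genes between the control populations (adjusted p = 0.0693). Failing it is therefore no evidence that a list did not move.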

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

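The tests of Slc12a8 were chosen only after its rise was seen. The dKO effect differed between ImCD4 and ImCD8 for 58 genes by the test of the difference itself, and each value below is the ImCD4 change minus the ImCD8 change on the log2 scale. It was positive for Il2rb (1.07), Cd160 (1.39), Uhrf1 (1.09), Slc2a3 (0.94), Pdgfb (3.30), Id2 (1.57), Etv5 (1.12), Myo1e (1.82), Mcm7 (0.54) and Mcm3 (0.62). It was negative for Zdhhc15 (-1.45), Zfp281 (-1.49), Mn1 (-2.42), Dusp10 (-0.78), Skil (-0.67), Gpr183 (-0.99), Aqp9 (-1.21), Il17rb (-1.92), Ccr7 (-0.85), Cd40lg (-1.13) and Socs3 (-2.48). When genotype was reassigned within each population, 5 of 100 splits, the real one included, gave 58 or more genes, the highest other giving 977. The 4 others all keep the real ImCD4 groups and mostly exchange those of ImCD8. They therefore carry the dKO effect itself, point to this structure of the samples and are no reference without change. The splits cannot decide on chance for the count, which is neither excluded nor shown.

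4 lists passed the test of the difference: CD8-lineage and cytotoxic genes (median 0.55), cell cycle genes (0.65), innate-like T cell genes (1.02) and glycolysis genes (0.17). None held with an estimated correlation, a setting under which no list passed in any contrast. Of 100 splits 43 gave 4 or more lists, up to 8, so chance is not excluded. Splits that keep part of the dKO effect are no reference without change, and a count of lists does not speak to particular ones. For the lists of the single contrasts 5 of 10 splits gave as many in ImCD4 (2 lists, highest other 8) and 5 of 10 in ImCD8 (3 lists, highest other 9). For single genes 1 of the 10 splits, the real one, gave the count in each contrast of 3 against 3. The counts were 1797, 822, 6058 and 5853 genes, against 0 in the highest other. 10 splits are too few for a share under 0.05. Each other split mixes the 2 real groups, so a real difference between them widens the spread within groups and lowers the count. The 0 is therefore no reference without change. For the 490 genes shared by both populations 1 of 100 splits gave as many, the highest other being 1, a share under 0.05. Other splits of a single population called 0 genes, which leaves almost nothing to share. These splits are thus no reference without change either and cannot decide whether the 2 effects are the same. Independent lists of these sizes would share 54.5 genes in the same direction if every gene were equally likely to be called.

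Among the genes taken by the naming rule, Slc12a8 had the largest rise in ImCD8 and the next largest after Ntn4 in ImCD4. It rose by 7.15 ± 0.21 in ImCD4 and 6.62 ± 0.23 in ImCD8 on the log2 scale. Among tested genes found in the annotation it is the next downstream of Zfp148 on the same strand, and starts 12965 bp after the end of Zfp148. The 16 other such genes within 1 Mb had a median of 0.0793 in ImCD4, which argues against a change of the whole region. Most of them lie on the other side of Zfp148. On the side of Slc12a8 the set holds only Heg1 and Umps, which changed by 0.05 and 0.18 in ImCD4 and did not pass. Transcription running on from the recombined Zfp148 allele may contribute to the rise of Slc12a8. It cannot be told apart from loss of repression by the factors, because counts per gene do not show whether reads join Zfp148 and Slc12a8. Loss of repression was not tested.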

How the results depend on the processing

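No paired analysis was run, because the labels give no replicate numbers and pairing by listed order would be an assumption. The last listed library of each group stood apart on the third component, so listed order may carry shared variation that the main model leaves in the error. The settings on the 4 libraries apart on the third component were chosen after the data were seen. Unless named, the cause was not tested. Of 157 results for named genes under 11 or 17 alternatives each, 124 kept direction and side of the threshold in all, 31 lost the call in at least 1, Zbtb7b and Prf1 in ImCD4 gained one in some (lowest adjusted p = 2.32e-08 and 0.000383) and none changed sign. Requiring a 2-fold change left 388 genes in ImCD4, 231 in ImCD8, 28 for the difference, 1947 between control ImCD8 and ImCD4 and 1781 between the dKO groups, by construction. Without the filter ImCD8 had 1280 genes and the difference 233, and DESeq2 gave 140 for the difference. A term for the 4 libraries gave 1420 in ImCD8, 200 for the difference, 811 shared genes and 4 lists in ImCD4. Without those libraries the difference had 106 genes, and 6 lists moved in ImCD4 and 6 in ImCD8. With 1 library left out at a time, counts ran from 1055 to 1482 in ImCD4, 473 to 838 in ImCD8, 39 to 65 for the difference, 5323 to 5569 and 4953 to 5454 between populations in control and dKO, and 312 to 459 for shared genes. The low values came without dKO ImCD4 replicate 2 (1055; control replicate 1 gave 1086) and without control ImCD8 replicate 1 (473 and 312). Which direction had more genes was not stable: it turned under 1 or more settings in all 5 contrasts, as in ImCD4 with the 6 libraries alone (935 higher, 1024 lower), in ImCD8 without dKO replicate 2 (447 and 391) and in the difference without control ImCD4 replicate 3 (23 and 24). Lists were the least stable: with an estimated correlation 0 moved in ImCD4, 0 in ImCD8 and 0 in the difference. Fry gave 7 in ImCD4 and 1 in the difference, and the stricter filter gave 1 in ImCD4 and 5 in ImCD8. The 7 include the list of partner and related genes of the 2 factors (fry adjusted p = 0.000174). That list holds Zfp148 and Zfp281 themselves, so its fall was partly set by the knockout. Leaving out 1 library gave 0 to 7 lists in ImCD4, with 0 without control replicate 3 or dKO replicate 1, 1 to 4 in ImCD8, with 1 without control replicate 1, and 4 to 6 in the difference. Depth limits genes near the floor, and changes of 0.5 on the log2 scale were often missed in the simulated data. A sex term was not run.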

Other observations

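Of the tests in this part, those of GC content and of shared control libraries were fixed before their results were seen, and the tests of depth, heat shock, cycling cells and ImCD8 cells were chosen afterwards. Some changes fell outside the main groups. Dntt, which encodes the enzyme that adds bases at receptor gene joins, rose by 0.79 ± 0.15 in ImCD4 and by 1.26 ± 0.15 in ImCD8 on the log2 scale. Bbc3, a gene of cell death, rose by 0.65 ± 0.10 and 0.56 ± 0.11, and was the only called member of 14 p53 targets in either population. Of 15 genes of the stress and unfolded protein response 5 rose in ImCD4 and 2 in ImCD8, Xbp1 and Mthfd2 in both, and the call of Xbp1 in ImCD8 was lost without single libraries (adjusted p up to 0.0701).

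4 libraries, the last listed of each group, scored 13.9 to 29.2 on the third component, and the other 8 scored -21.8 to -1.27. All 4 lay inside the depth range of the others, which argues against depth, and loadings had a Spearman correlation of -0.0226 with transcript GC across genes, which argues against GC content. The median loading of the heat shock list lay at percentile 100 of 10000 random lists matched on expression and that of the cell cycle list at percentile 0, so handling stress or a different share of cycling cells may lie behind the split. Chaperone and cell cycle genes had been noticed among the genes involved before these tests, which makes them weak evidence. The immature double-positive and T-lineage regulator lists also lay at percentile 0. Lists of cholesterol (0.05), regulatory T cell (0.18) and T cell receptor-induced genes (0.2) and of p53 targets (99.78) lay near an end too. The percentiles are therefore not specific to handling stress or cycling cells. The labels name no batch, a share of cycling cells can differ for technical or biological reasons, and the groups of the design give no biological explanation to test.

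With genes picked as at least 2-fold different between control ImCD8 and control ImCD4, those higher in ImCD8 had a median of 0.20 in the ImCD4 dKO contrast and those higher in ImCD4 a median of -0.21, a gap of 0.415 against at most 0.122 in 100 simulations with no dKO effect. Picked from the dKO libraries the gap was 0.0157 against -0.110 to -0.0550 simulated. Picked from the mean of both, where shared error cancels if control and dKO libraries vary alike, it was 0.191 against a simulated highest of 0.0397. The simulations drew each gene independently, while real genes vary together, with an estimated correlation of 0.33 for the cell cycle list. Their ranges may therefore be too narrow. Whether shared control libraries account for all of the gap is not settled. 3 tests of ImCD8 cells in the ImCD4 dKO sort came out differently, the second and the third being added after the results before them were seen: 107 genes at least 10-fold higher in ImCD8 gained a median of 1.25% of their ImCD8 level, with a lower quartile of 0.0124%, just above 0 as such cells may give, and 2 of the 10 most abundant of these genes gained 0.25 of the median share or less, which alone did not settle it. In the last, the fall of the genes higher in ImCD4, a median of -0.06 when picked from the mean, needs a share of 4.04%, while Itgae, at 0.802 CPM in ImCD4 dKO and 644 CPM in ImCD8 dKO (n = 3), allows at most 0.218% at its mean plus 2 SD and Nkg7, at 2.74 and 449 CPM, 1.07%, which argues against cells like the sorted ImCD8 cells as the source of the whole shift. CD8 cells low in both genes, a smaller share behind part of the shift and a smaller lineage difference in dKO stay open, and the gap from the mean in ImCD8 was -0.0946 against a simulated lowest of -0.0364.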
